A study of Dugesia japonica with 6 samples.

How the data were processed

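Poly(A)-selected RNA of whole, intact planarians of the species Dugesia japonica was sequenced from 6 libraries, 3 from animals adapted to adenosine dialdehyde (AdOx) and 3 from control animals. Per the labels' protocols, animals of about 1 cm were kept for 1 month in spring water with 100 µM AdOx, or in water with the acid vehicle alone, and each library was made from 6 individuals. Whether strand was used in counting is not given in the sources used here. Groups and replicate numbers were read from the sample titles. The labels do not say whether the 3 libraries of a group came from separate vessels, so the p-values measure the spread between these libraries, which may in part be technical.

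The deposited files of the 6 libraries hold raw counts of reads per transcript contig, as whole numbers, and list only contigs with at least 1 read, so a contig missing from a file was taken as 0. The contig IDs have the form that de novo transcriptome assembly gives, with a component part and a contig number, and every row carried such an ID. Bowtie2 2.2.3 and DESeq2 are named in the submitters' processing notes. The transcriptome, the counting step and the treatment of reads that match several contigs are not given in the sources used here. Contigs of 1 component can be near-identical, so counts may be split between them, and values were therefore also computed on component totals. A separate deposited table holds the authors' own comparison for 119 contigs, with a log2 fold change and its standard error, p-values and adjusted p-values, and, per the file headers, a mean normalized count and a Wald statistic (2 columns of unit score in the deposited table). All its adjusted p-values are under 0.01. The name of this table speaks of 2 replicates, and the libraries behind it were identified by refitting DESeq2 to each of the 9 ways of leaving out 1 library per group.

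The files do not pair contig IDs with gene names, and no annotation was used here. The 15 gene lists fixed before the data were examined (among them the methionine cycle, Wnt signalling and cell type markers) and the contigs of S-adenosylhomocysteine hydrolase were therefore not analysed here. For the same reason only 4 contigs are named, by a rule fixed before the data were examined: the 2 with the largest rise and the 2 with the largest fall in fold change among contigs with adjusted p under 0.05, a mean log2 CPM (read counts scaled to the size of the library) of at least 1, and all 3 AdOx libraries beyond all 3 control libraries.

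Total counts ranged from 15606794 to 20385026 per library. Contigs were filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3 at its defaults (minimum count 10, minimum total 15), which left 38728 of 44723 contigs, holding over 99.8% of the counts of each library. Libraries were scaled by TMM factors, and the groups were compared with edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The model held the group only, since the labels do not say that a replicate number marks a shared batch. The standard error of a fold change was taken as its absolute log2 value divided by the square root of the F statistic. CPM values are TMM-scaled, and log2 CPM values were computed with a prior count of 2. The pooled count ratio of a contig with few reads was given with an exact binomial (Clopper-Pearson) 95% interval, which covers counting error only.

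Counts were simulated with the means, dispersions and library sizes of these 38728 contigs. In them 200 contigs with a mean count of at least 20 were changed. The edgeR test recovered 88 of 100 contigs changed 2-fold and 100 of 100 changed 4-fold, with 16 false calls among 204. The simulated contigs varied independently, without deviations of a library or reads shared between contigs. These rates may therefore not hold for the real counts. Alternatives fixed before the data were examined were DESeq2 size factors, library totals, no filter, a mean CPM of at least 1, the DESeq2 1.42.0 Wald test, voom with sample quality weights of limma 3.58.1, the replicate number as a block, leaving out each library or each replicate number, and thresholds of 0.01 and 0.1. Component totals, the fits to the 4 libraries of the authors' table, and the comparison in the pair of libraries that the table left out were added after the data were examined. Random lists of the same size, drawn 10000 times from 50 bins of mean expression, gave the values expected of unselected contigs in that pair. A second set of lists, added after the first results were seen, was drawn from these bins cut into 5 by the SD within groups in the 4 libraries of the table, which leaves the pair out.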

Results

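The data consist of RNA-seq counts from intact planarians, flatworms that regenerate any missing body part, after 1 month in 100 µM AdOx or in control water. AdOx is an adenosine analogue that inhibits S-adenosylhomocysteine hydrolase (SAHH), the enzyme that clears the by-product of methyl transfer from S-adenosylmethionine. The study asked which genes were differentially expressed in animals that had become resistant to the inhibitor. Each group had 3 libraries of 6 animals. The AdOx libraries held 16963553, 15606794 and 16922374 counts, and the control libraries 20385026, 18687643 and 18167550. Reads were listed for 44723 contigs in 16760 components, of which 43394 contigs had reads in all 6 libraries.

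The correlation of log2 CPM across all tested contigs, which depends mostly on differences in abundance between contigs, averaged 0.986 ± 0.00266 (SD) over the 6 pairs of libraries within a group and 0.985 ± 0.00393 (SD) over the 9 pairs between groups, a difference smaller than the spread within either kind of pair. Over the 500 most variable contigs it averaged 0.820 ± 0.0419 (SD) within groups and 0.768 ± 0.0460 (SD) between groups. The first principal component held 35.7% of the variance and set AdOx replicate 2, at -54.1, apart from the other libraries, which lay between -5.23 and 28.1. The second held 20.5% and had AdOx replicates 1 and 3 at 27.8 and 23.5, control replicates 2 and 3 at -28.7 and -20.2, and AdOx replicate 2 and control replicate 1 between them at -4.40 and 2.08. Every pair of libraries differed by more than sampling noise, so all 6 were counted as separate libraries. The chi-square per degree of freedom ran from 2.17 (AdOx replicates 1 and 3) to 11.8 (AdOx replicate 2 and control replicate 1).

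After 1 month of AdOx, 57 of 38728 tested contigs had changed in abundance by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 31 of them higher and 26 lower than in control animals. The contigs that rose did so by a median of 1.82-fold and those that fell by a median of 1.67-fold, and 18 contigs changed at least 2-fold, 10 up and 8 down. Only 3 contigs changed by more than 4-fold, 2 of them up and 1 down. The called contigs covered a wide range of abundance, from 1.26 to 376 CPM with a median of 16.4. In all 57 the 3 AdOx libraries lay beyond the 3 control libraries, an arrangement that 14.5% of all tested contigs showed and that chance gives for 10%. Without adjustment, 3482 contigs had p under 0.05, against 1936 expected by chance. These 2 chance values are averages, and contigs that vary together can exceed them without an effect of AdOx. The count depended on the libraries: it fell to 16 without AdOx replicate 1, 28 without control replicate 1 and 9 without control replicate 3, and rose to 130 without AdOx replicate 2. The count at 2-fold or more and its balance moved too: it was 34 (25 up, 9 down) without AdOx replicate 2, 33 (23 up, 10 down) without AdOx replicate 3 and 8 (3 up, 5 down) without control replicate 3. With the replicate number as a block, which the labels do not tie to a shared batch, edgeR called 920 contigs, 464 higher and 456 lower, including all 57. DESeq2 called 131 contigs on the 6 libraries, 51 higher and 80 lower, including 47 of the 57. Without AdOx replicate 3, edgeR again called 57 contigs, of which 39 were the same. At 2-fold or more there were 46 (29 up, 17 down) with the block, 10 (4 up, 6 down) with DESeq2 and 11 (5 up, 6 down) on component totals.

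**Figure D1:**
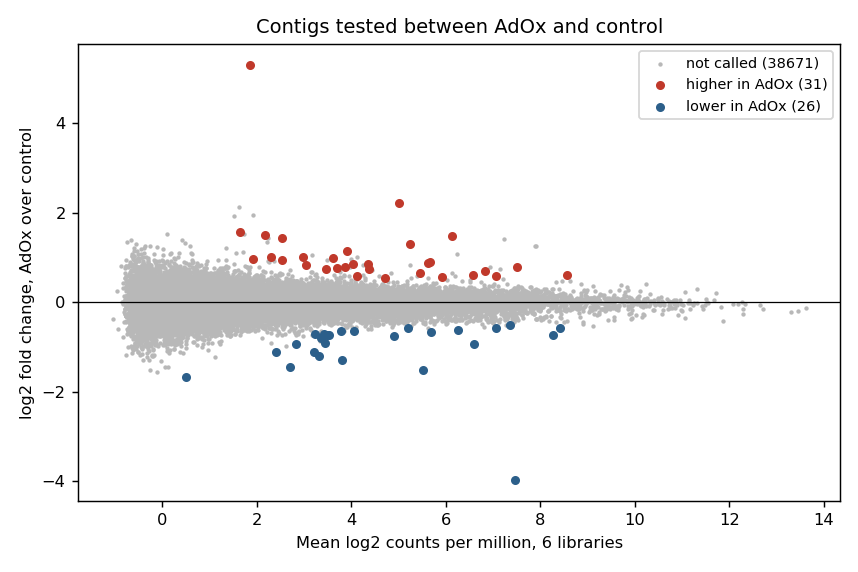
Log2 fold change (AdOx over control) against mean log2 CPM over the 6 libraries, 1 point per tested contig. The 31 contigs called higher in AdOx are red, the 26 called lower are blue and all others grey; 1 contig stands at 5.31 and 1 at -3.97, away from the rest.

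The largest rise was in contig comp134958_c0_seq1, which was almost absent from control animals. It had 68, 102 and 188 counts in the AdOx libraries and 5, 3 and 2 in the control libraries. Its abundance was 7.20 ± 3.53 CPM (SD, n = 3) in AdOx and 0.171 ± 0.0620 CPM (SD, n = 3) in control, a 42.0-fold difference of means. The edgeR log2 fold change was 5.31 with a standard error of 0.46 and an adjusted p of 3.46e-05. From the pooled counts of 358 and 10, the ratio was between 22.1 and 86.5 at 95% confidence for counting error alone. Contig comp130466_c0_seq2 rose from 11.6 ± 3.23 to 53.5 ± 7.90 CPM (SD, n = 3), or 4.60-fold, with an edgeR adjusted p of 7.36e-06.

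The largest fall was in contig comp138201_c0_seq1, from 334 ± 109 CPM in control to 21.3 ± 6.23 CPM in AdOx (SD, n = 3), or 15.7-fold. Its counts were 4678, 7972 and 6039 in the control libraries and 450, 359 and 245 in the AdOx libraries, and its edgeR log2 fold change of -3.97, with a standard error of 0.23, had an adjusted p of 3.22e-07. Contig comp139701_c0_seq3 fell from 67.5 ± 14.6 to 23.6 ± 6.13 CPM (SD, n = 3), or 2.86-fold, with an edgeR adjusted p of 0.000770. It is 1 of 2 contigs of its component, so its counts may be split with the other, whereas the first 3 named contigs are each the only contig listed for their component. All 4 contigs kept their direction when any library was left out, and each still passed edgeR's adjusted p threshold of 0.05.

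**Figure D2:**
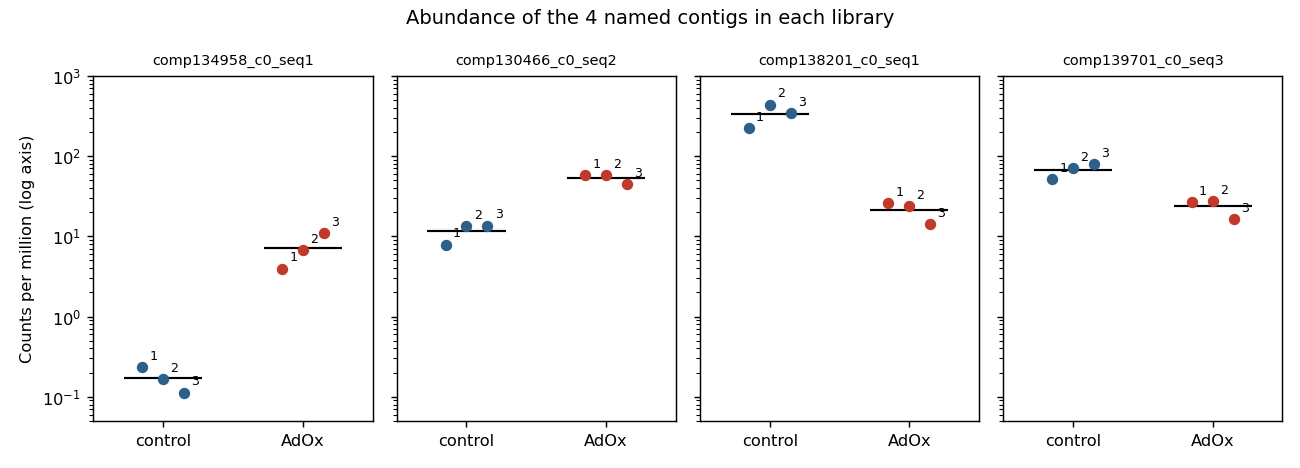
CPM (log axis, shared by the 4 panels) of the 4 named contigs in each library. Points are libraries, marked with their replicate number, and black lines are group means; the AdOx and control points do not overlap in any panel, and control values of comp134958_c0_seq1 average 0.171 CPM.

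Contigs of 1 component moved together where several were called. The 57 called contigs came from 51 components, and in each of the 6 components with 2 called contigs both moved the same way. When the counts of all contigs of a component were summed, 53 of 15448 tested components changed by the edgeR test, 25 higher and 28 lower. Where a component has only 1 contig, its total holds the same counts, so its call is no separate check. Of the 51 components with a called contig, 43 were called as totals and 8 were not. Of these 8, 7 had reads of other contigs, and in 5 of the 7 those reads moved the same way as the called contig. In 1 of the 5 they hardly moved, by 0.065 on the log2 scale against 1.505 for the contig. Contigs of 1 component may share reads, so their agreement is not independent.

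The authors' deposited table lists 119 contigs with an adjusted p under 0.01, of which 30 were higher and 89 lower in AdOx. Its median fold was 1.51 for the contigs listed as higher and 1.46 for those listed as lower, and 5 rises and 6 falls in the authors' deposited table reached 2-fold. The mean normalized counts in the authors' deposited table matched, to within 3.77e-13%, a DESeq2 fit to AdOx replicates 1 and 3 and control replicates 2 and 3. No other choice of 2 libraries per group came closer than a largest difference of 17.9%. In that fit 121 contigs passed an adjusted p of 0.01, and 117 of them were in the authors' deposited table. AdOx replicate 2 and control replicate 1 were thus not part of that comparison. Because the table was made from libraries that are also in the 6-library fit, its overlap with that fit is not independent evidence.

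With all 6 libraries, 118 of the 119 contigs kept the direction of the authors' deposited table, and 25 passed the edgeR test in that direction, 10 higher and 15 lower. This number also depended on the libraries: it was 6 without control replicate 3, 8 without AdOx replicate 1, 16 without AdOx replicate 3 and 57 without AdOx replicate 2. On all 6 libraries it was 57 with DESeq2, 64 (16 higher, 48 lower) with voom and 90 (20 higher, 70 lower) with the replicate block. Independent lists of the sizes of the 6-library calls and the table, drawn from all tested contigs, would share 0.0240 contigs among the rises and 0.0598 among the falls. The 2 lists were made from shared libraries, so these values are no test of their overlap. The other 32 of the 57 contigs called on 6 libraries were not in the authors' deposited table, and comp134958_c0_seq1, with the largest rise, was among them. Part of this follows from the filter and threshold behind the table: in the DESeq2 fit to its 4 libraries, 11 of the 32, comp134958_c0_seq1 included, had too low a mean count to be given an adjusted p (its mean was 66.2, and the lowest with an adjusted p was 139), 12 had an adjusted p from 0.01 to 0.05, 8 had 0.05 or more and 1 was under 0.01. When edgeR was fitted to the 4 libraries of the table alone it called 307 contigs, 119 higher and 188 lower, and these included all 57 of the 6-library calls.

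**Figure D3:**
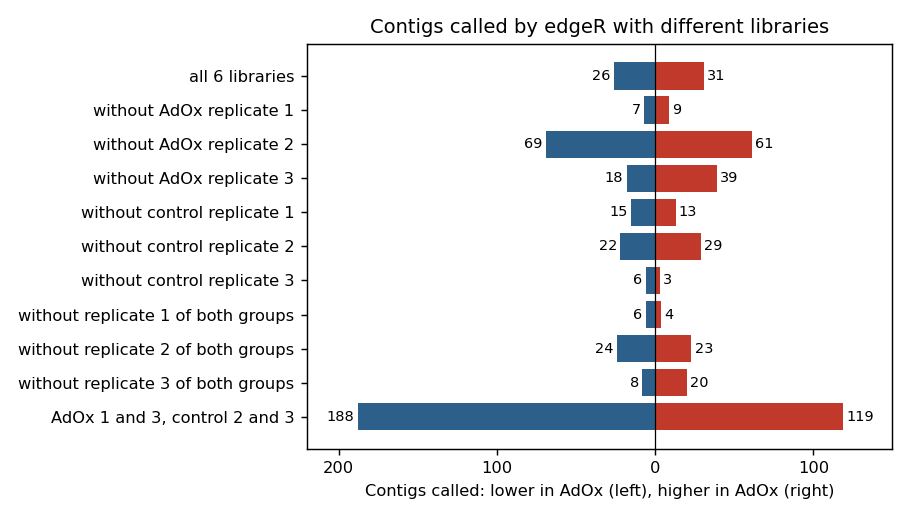
Number of contigs called by edgeR at an adjusted p of 0.05 with all 6 libraries and with libraries left out; red bars to the right are contigs higher in AdOx and blue bars to the left contigs lower in AdOx. The 6 libraries gave 31 and 26, and the 4 libraries behind the authors' deposited table gave 119 and 188.

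The pair of libraries that the table left out gave an unreplicated reading of the listed contigs. By chi-square per degree of freedom, AdOx replicates 1 and 3, which the table used, differed least of all pairs (2.17), and the left-out pair differed most (11.8). It sets AdOx number 2 against control number 1, whereas the table sets numbers 1 and 3 against 2 and 3, so an effect tied to the replicate number would enter the 2 comparisons with opposite sign. The random lists below do not allow for this. Over all tested contigs the log2 differences of the 2 comparisons correlated at 0.069, which does not exclude such an effect, since an effect of AdOx would act the other way. Of the 89 contigs listed as lower in the authors' deposited table, 59 were also lower in AdOx replicate 2 than in control replicate 1, where expression-matched random lists gave between 25 and 43 in their middle 95%. The median log2 difference of these 89 contigs was -0.54 in the libraries used and -0.14 in the pair left out, below the 0.02 to 0.20 of the random lists. The listed contigs were more variable in the 4 libraries used than these lists: the median SD within groups was 0.104 for the falls, against 0.068 to 0.096, and 0.128 for the rises, against 0.061 to 0.108. Lists matched on this SD as well gave 28 to 45 contigs lower and a median of -0.01 to 0.20, so the falls lay outside these too. Neither kind of list allows for contigs that vary together, and some falls share a component, so both ranges may be too narrow. Of the 30 contigs listed as higher, 14 were also higher in the pair left out, within the 13 to 24 of expression-matched lists and the 12 to 22 of lists matched on both, and their median log2 difference was -0.05 against 0.60 in the libraries used. The 30 rises were spread widely in the pair left out: 10 were higher by over 0.5 on the log2 scale and 5 lower by over 0.5.

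**Figure D4:**
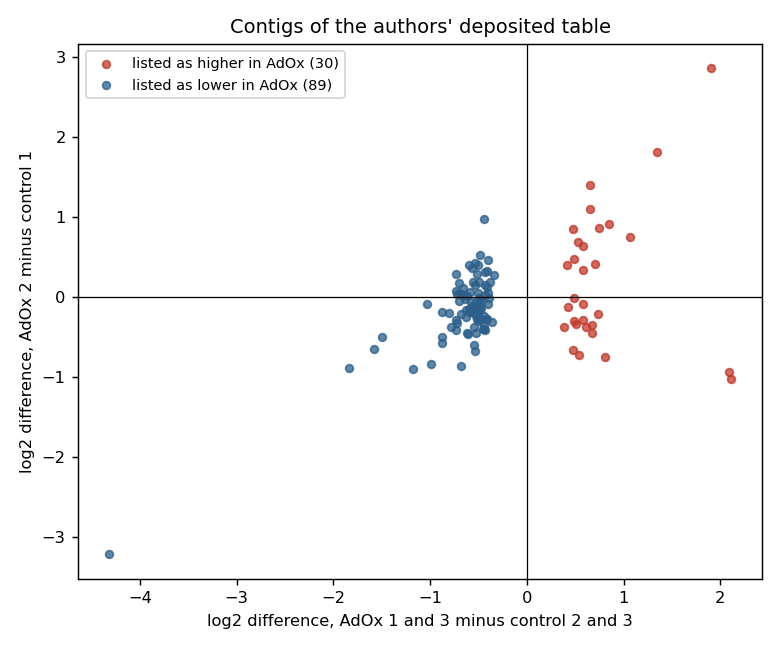
Log2 CPM difference between AdOx and control for the 119 contigs of the authors' deposited table: the 4 libraries the table used on the x axis, and AdOx replicate 2 minus control replicate 1, which it left out, on the y axis. Of the 30 contigs listed as higher (red), 14 lie above 0 on the y axis; of the 89 listed as lower (blue), 59 lie below it.

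The contigs with the largest rises in the authors' deposited table both had their lowest AdOx value in replicate 2 and their highest control value in replicate 1. The first had a log2 fold change of 2.22 in the authors' deposited table. Its abundance was 623, 114 and 280 CPM in AdOx replicates 1, 2 and 3 and 232, 102 and 90.8 CPM in control replicates 1, 2 and 3. With 6 libraries its edgeR log2 fold change was 1.26 with a standard error of 0.42 and an adjusted p of 0.366. The second, at 2.10 in the authors' deposited table, was at 342, 55.9 and 252 CPM in the AdOx libraries and 107, 72.9 and 65.5 CPM in the control libraries, and its 6-library edgeR log2 fold change of 1.41 had an adjusted p of 0.240.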

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

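The count of 57 contigs stayed within 1.5 times its value with DESeq2 size factors, library totals, no filter, a mean CPM of at least 1 and component totals. It was 131 with DESeq2's Wald test (10 at 2-fold or more, 57 shared in direction with the authors' deposited table), 170 with voom and quality weights (64 shared with the table), 18 at an adjusted p of 0.01 (10 at 2-fold or more, 12 shared) and 102 at 0.1. Leaving out libraries or replicate numbers gave from 9 (without control replicate 3) to 130 contigs (without AdOx replicate 2), from 8 to 34 at 2-fold or more, and from 6 to 57 shared with the table. Of the alternatives chosen after the data were examined, component totals gave 11 changed at least 2-fold, and the 4 libraries of the table gave 307 contigs with edgeR (43 at 2-fold or more) and 229 with DESeq2, each with 119 shared. The DESeq2 fit to these 4 libraries called 38 of the 57. Direction alone was shared by 118. The cause of these shifts was not tested, apart from the thresholds, which set the counts by construction. Over the 500 most variable contigs the mean correlation was 0.820 within and 0.768 between groups. The 4 named contigs kept their direction and call in all alternatives that gave an adjusted p; DESeq2 gave none for comp134958_c0_seq1. With the replicate block the fit called 920 contigs (46 at 2-fold or more, 90 shared with the table), including all 57. The deviations of same-numbered libraries from their group means correlated at 0.09, 0.33 and 0.13 for numbers 1, 2 and 3 over all tested contigs, where 1 pair missed the limit of 0.1, and at 0.28, 0.70 and 0.28 over the 14377 contigs with a mean log2 CPM over 3, where none did. Control replicate 1 correlated more with AdOx replicate 3 (0.12 and 0.36) than with its own number. Over the abundant contigs AdOx replicate 1 correlated with control replicate 3 at 0.17, also above that limit. The deviations of a group's 3 libraries cancel, so the 3 values are not independent. A likeness of the libraries numbered 2 alone can make those numbered 1 and 3 correlate positively, same-numbered or not. Whether the numbers pair the libraries thus stays open. The fit without the block, fixed before the data were examined, was kept, and the count with the block was known when this was judged. The gene list and SAHH comparisons were not run, because the files give no gene names. With these libraries the smallest rise called was 1.45-fold and the smallest fall 1.42-fold.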

Other observations

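The tests of exchanged labels, of regression to the mean with both kinds of random list, of contigs without other reads in their component and of the splits of the 6 libraries by contig calls, and the bound of 75% for a kept fold, were chosen only after the results they measure had been seen.

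Differences of 4-fold or more within a group were rare among abundant contigs, while smaller differences were not counted. Among 4845 contigs with a mean log2 CPM of at least 5, 3 contigs of 2 components differed by 4-fold or more between libraries of the same group. In all 3 the library farthest from its group's median was AdOx replicate 2. None of the 3 was called on 6 libraries, and 2 of them are the contigs with the largest rises in the authors' deposited table.

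Of the 30 contigs that the authors' deposited table lists as higher in AdOx, 16 were not higher in AdOx replicate 2 than in control replicate 1, the pair it left out. By the count of calls, the tables argue against exchanged labels of these libraries: with the labels exchanged edgeR called 4 contigs, against 57 with the labels as given. By chi-square per degree of freedom, AdOx replicate 2 was nearer control replicate 2 (4.74) than AdOx replicates 1 and 3 (6.32 and 7.15). It was far from control replicates 1 and 3 (11.8 and 10.3). Control replicate 1 was nearest AdOx replicate 3 (4.06), then control replicate 3 (4.71), AdOx replicate 1 (5.40) and control replicate 2 (6.14). The libraries thus do not all lie nearest to their own group. Regression to the mean after selection on the 4 libraries may account for the 16 contigs, and stays open. The 5 contigs that were lower by over 0.5 in the left-out pair exceeded the 0 to 4 of expression-matched random lists but lay inside the 0 to 6 of lists matched also on the SD within groups in the 4 libraries used. The first lists were less variable in those libraries, with a median SD of 0.061 to 0.108 against 0.128 for the 30 contigs, so the bound set for this test was too narrow. A deviation that AdOx replicate 2 shares with control replicate 2 may also account for it: across the 30 contigs, control replicate 2 minus control replicate 3 correlated with AdOx replicate 2 minus control replicate 1 at r = 0.375, inside the 0.24 to 0.83 of random lists, so the 30 contigs do not stand apart and this too stays open. A biological difference of AdOx replicate 2, such as incomplete adaptation of its animals, was not tested.

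Of the 51 components with a called contig, 8 were not called as totals. In 5 of these the total kept at least 75% of the contig's log2 fold and missed the threshold of 0.05, with adjusted p from 0.059 to 0.099; a missed threshold does not show that these totals were unchanged. The tables argue against reads assigned differently among near-identical contigs for 1 of these 5, which has no other reads in its component. This outcome was fixed by the make-up of the component, whose total holds the same counts (log2 fold 0.86 as a contig and 0.84 as a total). In the other 3 components the log2 fold fell from 1.301 to 0.881, from 0.586 to 0.178 and from 1.505 to 0.107. Such assignment may account for contigs with other reads in their component, and stays open. Of these 7, 5 (71.4%) had the remaining reads moving the same way as the contig, 1 of them by only 0.065 on the log2 scale. This share lies between the outcomes that would have decided, and 7 contigs are too few to settle it.

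The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 57 contigs, and the highest of the others gave 5. For contigs changed at least 2-fold the values were 18 and 3, and for component totals 53 and 1. In each case 1 split, the real one, gave as many calls.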
